A study of Mus musculus with 8 samples.

How the data were processed

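Total RNA of snap-frozen liver from C57BL/6 mice was extracted with Trizol, and 300 ng per sample were labelled with a whole-transcript kit and measured on 1-colour Affymetrix arrays, per the labels' protocols. There were 8 samples, 4 labelled rilpivirine and 4 labelled control, with replicate numbers 1 to 4 in each group. The authors deposited log2 expression values for 41345 probe sets, made with RMA, a method that corrects background, normalizes arrays by quantiles and summarises probes into probe sets, and compared with limma, per the submitters' processing notes; versions are not given in the sources used here. RMA shares its normalization across arrays and so removes differences in total signal between samples; a change in the total amount of mRNA could not be seen. The values ran from 0.696 to 13.4. No pair of arrays was identical. The RNA's integrity was checked on a Bioanalyzer per the labels, but integrity values, collection times, hybridization batches and the diet of each sample are not given in the sources used here.

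Probe sets were named through the platform annotation: 23521 had 1 gene symbol, 1814 had several and 16010 had none listed. Only probe sets with 1 symbol were used, and of several for a symbol the one with the highest mean over all 8 arrays was kept, giving 22180 genes. The Entrez identifiers of 21994 of these genes were found in the RefSeq gene table, and 0 symbols needed an update. Genes with a mean under the 25th percentile (2.72 log2) were left out, 5545 of them, and 16635 were tested. The other 24710 probe sets were tested apart from the genes: limma called 0 of them past an adjusted p of 0.05, with 1274 at an unadjusted p under 0.05.

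Differences between rilpivirine and control were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates or block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Confidence intervals are 95% intervals of that fit. A total of 33 gene lists (20 of pathways and 13 of cell types) with 775 distinct genes, of which 649 were measured, was fixed before the data were examined, and 32 lists had at least 5 measured members. Lists were tested with camera at a correlation of 0.01 between genes, with adjustment over the 32 lists; camera with estimated correlation and fry were alternatives. The scripts were tested on simulated data with known changes in 16635 genes: 5.37% of the genes called were false, and a shift of -0.3 log2 in lists of 30 independent genes was recovered in 100% of cases with 0% of unshifted lists called. The simulated genes were independent, so this says nothing about lists whose genes vary together.

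The named genes followed a rule fixed before the data were examined. It took up to 12 genes in each direction past the threshold with the largest change; as none passed, genes with the smallest unadjusted p whose groups did not overlap took their place, and are given as values. Receptors of smell, predicted genes and non-coding small RNAs were not named in this part. It also took the 3 members with the smallest p of each list that the text describes, and a fixed set of 11 genes, of which 1 is not reported here. The 8 lists past the threshold and 8 others close to the question of fatty liver, fibrosis and drug metabolism were described; the choice of these other 8 was made after values had been seen. Further members of the acute phase and clock lists were named after their values were seen.

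Alternatives chosen before the data were examined were eBayes with trend and robust moderation, array weights, centring of each array on its median, a further quantile normalization, no filter or a filter at the 50th percentile, the mean of all probe sets of a gene, the replicate number as a block, each sample left out in turn, Welch statistics per gene, other list tests and other thresholds. Alternatives without rilpivirine replicates 1 and 2 together, the 2 arrays with the highest scores on the first principal component (45.0% of the variance), and with the mean level of 72 small nucleolar RNA probe sets as a covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.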

Results

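Liver RNA of C57BL/6 mice was measured in 8 samples on Affymetrix whole-transcript arrays, with an array for each sample. 4 samples came from animals given rilpivirine, a non-nucleoside inhibitor of the reverse transcriptase of HIV that is taken daily in antiretroviral therapy, and 4 came from a control group. The labels give non-alcoholic fatty liver disease for all 8 samples. They mention a normal diet and a 60% fat diet over 3 months without saying which sample had which, and give the daily oral dose only as equivalent to that of patients. The comparison asks which liver transcripts differ with rilpivirine in fatty liver. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between samples labelled as replicates, which may be technical. With 4 arrays per group, their number limits the precision. The array medians lay between 3.33 and 3.45 on the log2 scale, and the correlations between arrays ranged from 0.956 to 0.990. Rilpivirine replicate 2 stood apart: its mean correlation with the other arrays was 0.967, against 0.979 to 0.984 for the others, and its small nucleolar RNA probe sets lay 0.49 log2 above the mean of the 8 arrays, against -0.63 to 0.28 elsewhere. Xist, which is transcribed from the inactive X chromosome, measured 6.69 to 8.68 log2 in all 8 samples, while the Y-linked genes Kdm5d, Uty and Eif2s3y reached at most 2.53.

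**Figure D1:**
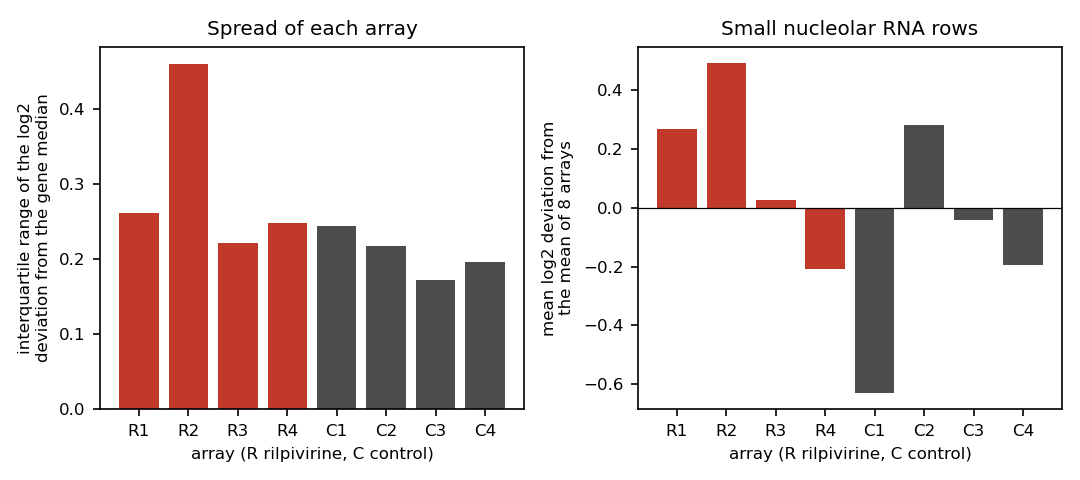
Left, the interquartile range of each array's log2 deviations from the gene medians; right, the mean log2 deviation of the 72 small nucleolar RNA probe sets from the mean of the 8 arrays; R marks rilpivirine and C control samples, numbered by replicate. Rilpivirine replicate 2 has a range of 0.460, against 0.173 to 0.261 in the other arrays, and the small nucleolar RNA level spans -0.63 in control replicate 1 to 0.49 in rilpivirine replicate 2.

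No single gene passed the threshold over all genes, and the genes with the smallest p-values are given as values. Transcripts of Cldn1, which encodes the tight junction protein claudin 1, measured 8.64 ± 0.19 log2 (SD, n = 4) with rilpivirine and 7.89 ± 0.16 (SD, n = 4) in controls, a 1.68-fold higher level. Tjp3, which encodes a scaffold protein of tight junctions, was 1.74-fold higher, and Coq8a, needed for coenzyme Q synthesis, was 1.97-fold higher. Gldc, of the glycine cleavage system, and Hsd3b7, an enzyme of bile acid synthesis, had levels 1.61-fold and 1.51-fold those of controls. The other genes named on the higher side were Tuba1c, Ccr7, H2bc3, Usp17la, Pde9a, Crip2 and Drd5, with log2 differences of 0.57 to 1.12. Usp17la and Drd5 were dim, at means of 3.15 and 3.11 log2 in controls, near the filter value of 2.72. A second probe set of Drd5 had a log2 difference of -0.08, and a second, dim probe set of Tuba1c one of 0.24. On the lower side, Marveld1, a membrane protein with a MARVEL domain, had a log2 difference of -0.95 ± 0.15 (SE). Lcn2, the secreted iron-siderophore binding protein lipocalin 2, had a difference of -1.16 ± 0.20 (SE), and Nmrk1, a nicotinamide riboside kinase, one of -1.11 ± 0.24 (SE). Gne, which makes the precursor of sialic acid, had a difference of -0.67 ± 0.13 (SE). Lrg1, Ctrcos, Slc13a3, Pdp2, Clmn, Gas2l2, Usp2 and Rarres1 completed the lower side, with differences of -1.60 to -0.53. Gas2l2 was also dim, at a mean of 3.27 log2 in controls and 2.75 with rilpivirine. In each of the 24 genes named here the 4 rilpivirine and 4 control values did not overlap, which was a condition for naming them.

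Of 16635 genes tested with limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05 or of 0.10, and the smallest adjusted p was 0.595. At an unadjusted p under 0.05 limma gave 867 genes, 333 higher and 534 lower with rilpivirine, where chance alone gives 832. Each alternative setting or test that was tried also called 0 genes after adjustment. Leaving out rilpivirine replicate 4 raised the 867 to 1524. The share of higher genes among them was 38.4%, and 57.8% after each array was centred on its median, or 51.1% after a further quantile normalization. The groups did not overlap in 505 genes, 3.04% of those tested, and chance gives 2.86%. On simulated data of the same size the test recovered 19.1% of genes changed by 0.5 log2, 70.7% of those changed by 1 and 98.2% of those changed by 2. The simulated genes were independent and every simulated array was equally noisy. These shares may therefore be too high for the real arrays, of which rilpivirine replicate 2 stood apart.

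Gene lists had been fixed before the data were examined. Of 32 lists, 8 passed an adjusted p of 0.05 in camera, a competitive test of a list's genes against all others, at a preset correlation of 0.01 between genes. 3 lists were higher with rilpivirine: sinusoidal endothelial markers, cell cycle and skeletal muscle markers. 5 were lower: STAT3 targets and acute phase proteins, the circadian clock, markers of monocytes and lipid-associated macrophages, autophagy and lysosome, and Kupffer cell markers. With the correlation between genes estimated for each list, 0 of the 8 calls held, and the smallest adjusted p was 0.321. The rotation test fry, which asks whether a list's genes move on balance in a single direction, called 0 lists (smallest adjusted p 0.154); its mixed form, which counts changes in either direction, called only the acute phase list of the 32 (adjusted p = 0.0252).

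**Figure D2:**
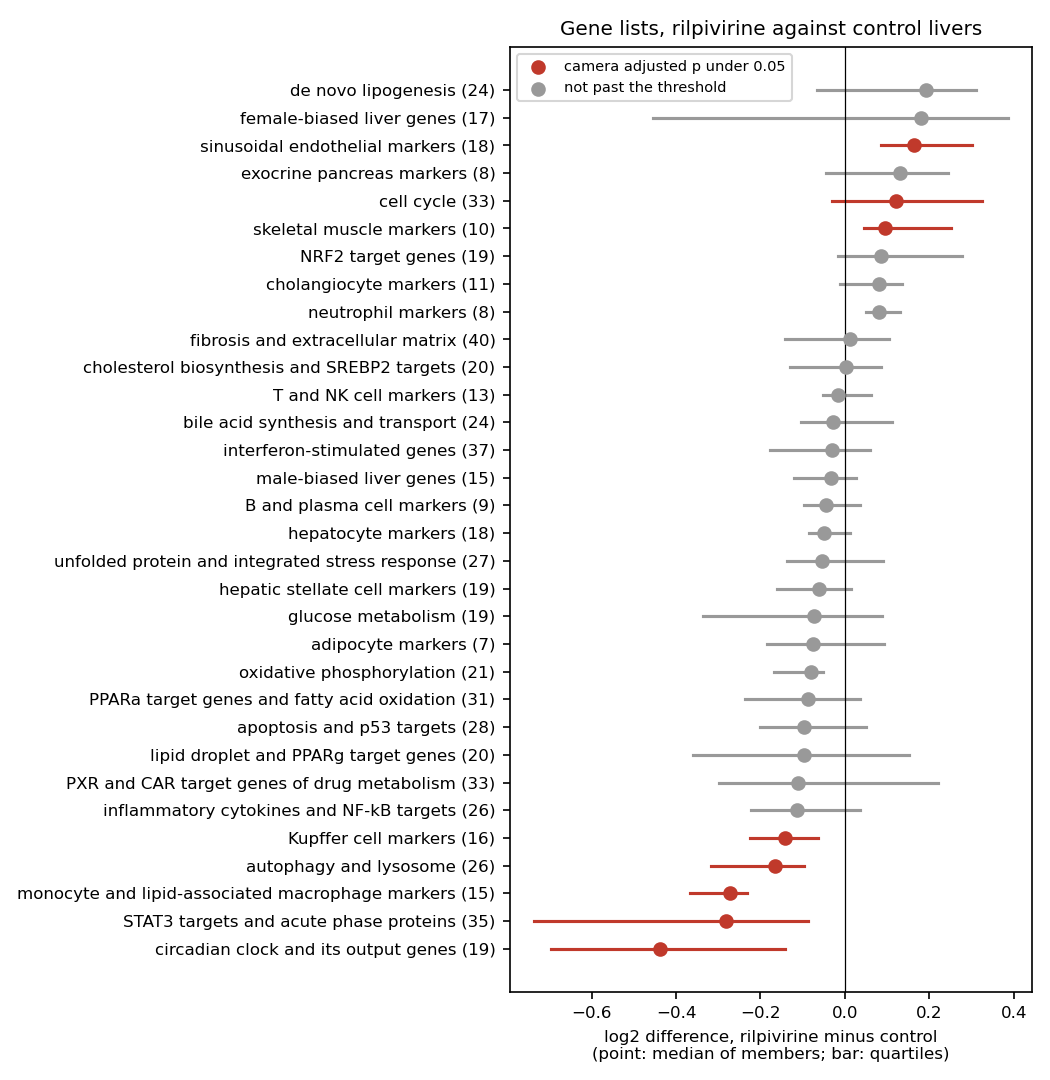
Median log2 difference, rilpivirine minus control, of the measured members of each of 32 gene lists (points), with the quartiles over members (bars) and the number of members in brackets; red marks lists past an adjusted p of 0.05 in camera with the preset correlation. The clock list has a median of -0.44 and the acute phase list one of -0.28, while the fibrosis list lies at 0.01.

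Acute phase transcripts fell in the livers of the rilpivirine group as a list in camera (adjusted p = 2.97e-10 at the preset correlation, and adjusted p = 0.321 with an estimated correlation). Of 35 measured STAT3 targets and acute phase proteins, which hepatocytes secrete or induce in response to interleukin 6, 32 were lower and 3 higher, and the median log2 difference was -0.28. Over all genes 0 members passed; 4 members fell when adjusted over the list alone. Lcn2 fell to 7.18 ± 0.27 log2 (SD, n = 4) from 8.34 ± 0.37 (SD, n = 4) in controls, and Lrg1, a leucine-rich glycoprotein of plasma, to 9.04 ± 0.14 from 9.70 ± 0.06 (SD, n = 4 each). Orm3, an orosomucoid, was 2.29-fold lower, and the metal-binding metallothionein Mt2 fell to a mean of 8.57 log2 from 10.57 (SE of the difference 0.56, n = 4 each). At an unadjusted p under 0.05, 13 members were lower and 0 higher. Stat3 itself had a log2 difference of -0.30 ± 0.12 (SE), with an adjusted p of 0.890 in limma. The fibrinogen chains Fga, Fgb and Fgg differed by -0.09, -0.11 and -0.06 log2, and Socs3, a feedback target of STAT3, by 0.04 ± 0.14 (SE). The list mean per sample, as a deviation from the mean of 8 arrays, ran from -0.36 to -0.07 log2 with rilpivirine and from -0.03 to 0.37 in controls.

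Without rilpivirine replicates 1 and 2 together, a choice made after the data were seen, the median of the acute phase list was -0.14, and the camera adjusted p was 1.19e-06. The 4 members called over the list alone became 2 without rilpivirine replicate 2 or control replicate 1, 3 or 4, and 9, 8 and 12 without rilpivirine replicate 3, rilpivirine replicate 4 and control replicate 2. They became 9 with array weights, 10 with the replicate block, and 2 after a further quantile normalization or with the small nucleolar RNA covariate.

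**Figure D3:**
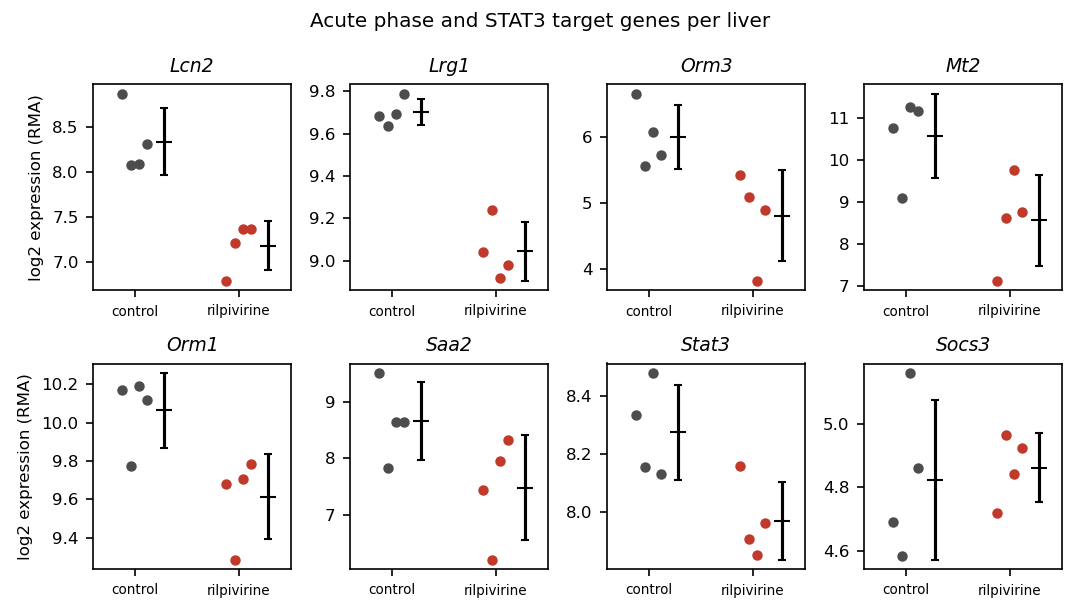
Expression (log2, RMA) of 8 members of the acute phase list in each liver sample (points, in replicate order from left to right), with the group mean and SD (bars); the 8 were chosen for drawing after their values were seen. The 4 rilpivirine values of Lcn2, Lrg1 and Orm3 lie below all 4 control values, while those of Socs3 lie within the control range.

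Clock genes differed between the groups as a list in camera, with members in both directions (adjusted p = 9.30e-05 at the preset correlation, and adjusted p = 0.321 with an estimated correlation). Of 19 measured genes of the circadian clock and its outputs, 15 were lower and 4 higher with rilpivirine, with a median log2 difference of -0.44. Over all genes 0 passed; adjusted over the list alone, 10 genes fell and 3 rose. Usp2, a rhythmically expressed deubiquitinase, fell to 6.52 ± 0.84 log2 from 8.12 ± 0.37 (SD, n = 4 each), a 3.03-fold lower level. Wee1, a kinase that restrains entry into mitosis and is driven by the clock, was 2.17-fold lower. The output transcription factors Dbp and Tef were 1.84-fold and 1.48-fold lower. The period and cryptochrome repressors Per1, Per3, Cry1 and Cry2 fell by 0.55, 0.81, 0.47 and 0.44 log2, and Ciart and Bhlhe41 fell by 0.91 and 0.32. The genes that rose were Arntl, which encodes the activator BMAL1 and was 1.61-fold higher, its partner Npas2, with a difference of 0.49 ± 0.17 log2 (SE), and Nr1d1, which encodes the repressor REV-ERB alpha, with 0.67 ± 0.22 (SE). Clock, the other partner of BMAL1, had a difference of 0.14 ± 0.38 (SE).

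The clock list stayed past camera's threshold at the preset correlation with every sample left out in turn, but the 13 members called over the list alone became 5, 8, 2 and 7 without rilpivirine replicate 2, rilpivirine replicate 4, control replicate 3 and control replicate 4.

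**Figure D4:**
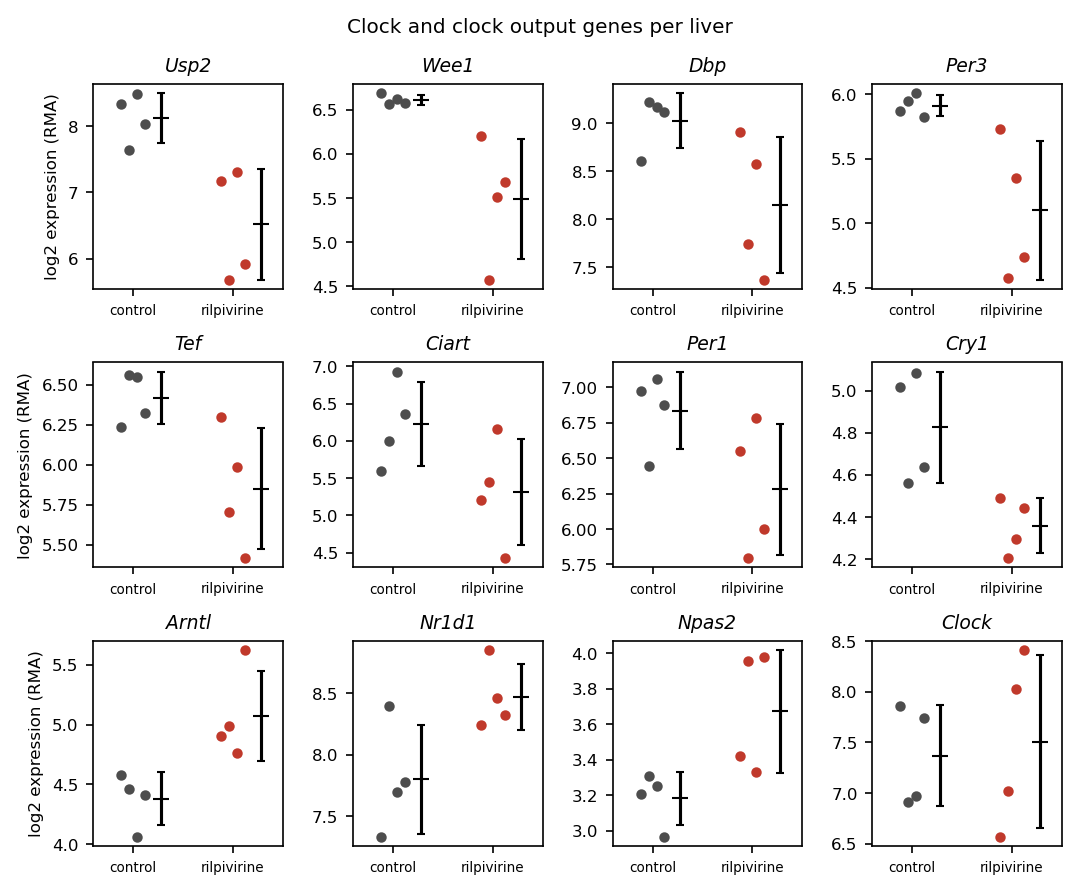
Expression (log2, RMA) of 12 clock and clock output genes in each liver sample (points, in replicate order from left to right), with the group mean and SD (bars); the 12 were chosen for drawing after their values were seen. The 4 rilpivirine values of Usp2 and Wee1 lie below all 4 control values and those of Arntl above them, while the values of Clock overlap.

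Markers of liver sinusoidal endothelial cells, which line the capillaries of the lobule, rose as a list in camera (adjusted p = 9.64e-06, and adjusted p = 0.804 with an estimated correlation). Of 18 members 17 were higher and 1 lower, with a median log2 difference of 0.16, and 0 members passed over the list alone. Kdr, a receptor of vascular endothelial growth factor, had a difference of 0.43 ± 0.17 (SE), Oit3 one of 0.40 ± 0.17 (SE), and the scavenger receptor Stab2 one of 0.40 ± 0.17 (SE). The median was 0.25 without rilpivirine replicate 4, where 2 members passed over the list alone, 0.25 after a further quantile normalization, and 0.10 without rilpivirine replicates 1 and 2 together, where the camera adjusted p was 0.0736.

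Macrophage markers fell as lists at the preset correlation. Of 16 Kupffer cell markers, of the resident macrophages of the liver, 14 were lower and 2 higher, with a median log2 difference of -0.14 (camera adjusted p = 0.0269, and adjusted p = 0.871 with an estimated correlation). The complement genes C1qa and C1qb had differences of -0.33 ± 0.11 and -0.50 ± 0.14 (SE), and C1qc one of -0.22 ± 0.14 (SE). Of 15 markers of monocytes and lipid-associated macrophages 14 were lower and 1 higher, with a median of -0.27 (camera adjusted p = 0.00426, and adjusted p = 0.871 with an estimated correlation). Ms4a7 had a difference of -0.49 ± 0.20 (SE), Trem2, a lipid-sensing receptor of macrophages, one of -0.32 ± 0.14 (SE), and Plac8 one of -0.35 ± 0.18 (SE). In both lists 0 members passed over the list alone. The Kupffer call ended without rilpivirine replicate 4 (median -0.03), control replicate 3 (-0.11) or control replicate 4 (-0.11), after a further quantile normalization (-0.06) and among genes above the median level (adjusted p = 0.0849), while without rilpivirine replicate 3 the median was -0.22. The monocyte call ended without rilpivirine replicate 2 (-0.13) or control replicate 1 (-0.14), among genes above the median level (adjusted p = 0.0622), without rilpivirine replicates 1 and 2 together (0.02), and with the small nucleolar RNA level as a covariate (-0.04), while without rilpivirine replicate 4 the median was -0.47. Rilpivirine replicate 2, the array with the highest small nucleolar RNA level (0.49 log2 above the mean), had the lowest mean of the monocyte markers, -0.57 log2 from the mean of 8 arrays.

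The cell cycle list rose, with 24 of 33 members higher, 9 lower and a median log2 difference of 0.12. In camera its adjusted p was 0.00156, and adjusted p = 0.875 with an estimated correlation. Cdc20 and Cdkn3, both of mitosis, had differences of 0.57 ± 0.17 and 0.64 ± 0.26 (SE), whereas Ccne1, the cyclin of entry into DNA replication, had one of -0.57 ± 0.17 (SE). Cdkn3 measured 4.31 log2 in rilpivirine replicate 4, against 2.80 to 3.28 in the rest of its group. Its mean in controls was 2.75, near the filter value of 2.72. Without rilpivirine replicate 4 the median was 0.06 (camera adjusted p = 0.272), without rilpivirine replicate 2 it was 0.27, without rilpivirine replicates 1 and 2 together 0.32, and with the small nucleolar RNA covariate 0.23.

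The autophagy and lysosome list fell, with 21 of 26 members lower, 5 higher and a median of -0.17. Camera gave an adjusted p of 0.00734, and adjusted p = 0.871 with an estimated correlation. Ulk1, the kinase that starts autophagy, had a difference of -0.36 ± 0.14 (SE), the mitophagy receptor Bnip3 one of -0.63 ± 0.26 (SE), and Gabarap one of -0.30 ± 0.13 (SE), with 0.21 in a second, dimmer probe set of Gabarap. The call ended without rilpivirine replicate 2 (median -0.12, camera adjusted p = 0.0877), without rilpivirine replicates 1 and 2 together (-0.10), and with the small nucleolar RNA level, which was highest in replicate 2, as a covariate (-0.08).

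Of 10 measured skeletal muscle markers 9 were higher and 1 lower, with a median of 0.10 at low levels. Camera gave an adjusted p of 0.0233, and adjusted p = 0.871 with an estimated correlation. Atp2a1 measured 3.60 ± 0.22 log2 with rilpivirine and 3.26 ± 0.16 in controls (SD, n = 4 each), Ckm had a difference of 0.28 ± 0.13 (SE) and Myh4 one of 0.27 ± 0.20 (SE). The call ended without rilpivirine replicate 2 (median 0.02) or 3 (0.11), without control replicate 1 (0.12) or 3 (0.06), among genes above the median level (0.08), without rilpivirine replicates 1 and 2 together (0.003) and with the small nucleolar RNA covariate (-0.01). The median was 0.23, 0.16 and 0.06 without rilpivirine replicate 4, control replicate 2 and control replicate 4, and 0.17 after a further quantile normalization. In the cell cycle, autophagy and muscle lists 0 members passed over the list alone.

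None of the fibrosis, stellate cell, inflammation and interferon lists passed the threshold over all 8 arrays, and no member passed after adjustment over its list alone or over all genes. Before adjustment, Timp3, Cygb, Cxcl1, Il1r1, Oasl1 and Igtp had an unadjusted p under 0.05 in limma, and the groups did not overlap in Cygb, Cxcl1 and Igtp. Of 40 measured fibrosis and extracellular matrix genes 21 were higher and 19 lower, with a median log2 difference of 0.01 (camera adjusted p = 0.687). Col1a1, a chain of type I collagen, differed by 0.01 (95% confidence interval -0.57 to 0.59). Acta2, a marker of activated stellate cells, differed by 0.11 ± 0.16 (SE), and Tgfb1 by 0.02 ± 0.11 (SE). Timp3, an inhibitor of matrix proteases, differed by -0.39 ± 0.14 (SE), Eln by 0.24 ± 0.12 and Mmp14 by 0.24 ± 0.14 (SE). The median of 19 hepatic stellate cell markers was -0.06 (camera adjusted p = 0.480), and was 0.01 without rilpivirine replicate 1, -0.14 without rilpivirine replicate 4 and 0.01 after a further quantile normalization; Cygb differed by -0.33 ± 0.10, Des by -0.28 ± 0.13 and Ngfr by 0.30 ± 0.20 (SE). Among 26 inflammatory cytokines and NF-kB targets 17 were lower and 9 higher (median -0.11, camera adjusted p = 0.259), and the median was -0.05 without rilpivirine replicate 2, -0.06 without control replicate 1 and 0.003 without rilpivirine replicates 1 and 2 together. Tnf differed by 0.17 ± 0.19, Ccl2 by 0.04 ± 0.21, the chemokine Cxcl1 by -0.49 ± 0.18, Il18 by -0.25 ± 0.17 and the interleukin 1 receptor Il1r1 by -0.97 ± 0.42 (SE). Of 37 interferon-stimulated genes 21 were lower and 16 higher, with a median of -0.03 where camera's direction was up (adjusted p = 0.914); Oasl1 differed by 0.54 ± 0.19, Igtp by 0.40 ± 0.15 and Psmb8 by -0.29 ± 0.14 (SE). Their median was 0.05 without rilpivirine replicate 2, -0.07 without rilpivirine replicate 4 or control replicate 3, 0.01 after centring of the arrays and 0.04 after a further quantile normalization. The fibrosis median was -0.10 without rilpivirine replicate 4 (31 of 40 members lower), -0.01 without control replicate 3, -0.04 without control replicate 4 and 0.11 without rilpivirine replicates 1 and 2 together (camera adjusted p = 0.0270). Without rilpivirine replicate 4, Col1a1, Acta2, Tgfb1 and Ccl2 differed by -0.17, -0.01, -0.03 and -0.15. Without rilpivirine replicates 1 and 2 together the interferon median was 0.05 (camera adjusted p = 0.00571), and with the small nucleolar RNA covariate it was 0.06 (0.0326).

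Drug metabolism and lipid lists did not pass the threshold. Of 33 targets of the xenobiotic receptors PXR and CAR 20 were lower and 13 higher (median -0.11, camera adjusted p = 0.698). The median was -0.05 and -0.002 without rilpivirine replicates 1 and 2 in turn, -0.17 and -0.18 without rilpivirine replicates 3 and 4 in turn, -0.07 without control replicate 1, -0.22 without control replicate 2, and 0.02 with the small nucleolar RNA covariate. Cyp3a11 and Cyp2b10, inducible through PXR and CAR, differed by -0.20 ± 0.25 and -0.23 ± 0.38 log2 (SE). Cyp3a11 turned to 0.24 without rilpivirine replicates 1 and 2 together and to 0.13 with the covariate, and Cyp2b10 to 0.15 without control replicate 3. Cyp3a13 differed by -0.67 ± 0.18, Cyp2a4 by -0.52 ± 0.20 and Cyp2c29 by 0.35 ± 0.12 (SE), with -0.002 in a second, dim probe set of Cyp2c29. Of 24 genes of de novo lipogenesis 17 were higher and 7 lower, with a median of 0.19 (camera adjusted p = 0.0647). Srebf1, a master regulator of lipogenesis, differed by 0.26 ± 0.29, Pklr by 0.32 ± 0.18, Thrsp by -0.90 ± 0.44 and Dgat2 by -0.24 ± 0.14 (SE). Thrsp ran from 7.71 to 10.09 log2 within the rilpivirine group and from 9.31 to 9.91 in controls. Srebf1 turned to -0.02 without rilpivirine replicates 1 and 2 together. The lipogenesis list passed the threshold without rilpivirine replicate 2 (median 0.22, adjusted p = 0.00213), rilpivirine replicate 3 (0.25, 0.000223) or control replicate 3 (0.21, 0.0311), with array weights (0.24, 0.0180) and among genes above the median level (0.19, 0.0136). Without rilpivirine replicate 1 its median was 0.06 (adjusted p = 0.979), without rilpivirine replicate 4 it was 0.05 (0.352), and without rilpivirine replicates 1 and 2 together 0.08 (0.924). Of 31 PPARa targets and fatty acid oxidation genes 21 were lower and 10 higher (median -0.09, camera adjusted p = 0.216), and the list passed without control replicate 2 (-0.14, adjusted p = 0.0473), whereas the median was -0.04 without rilpivirine replicate 1 and 0.01 with the small nucleolar RNA covariate. Ppara differed by -0.41 ± 0.15, Acot3 by -0.60 ± 0.22 and Acot4 by -0.59 ± 0.25 (SE), with 0.01 in a second probe set of Acot4. Of 20 lipid droplet and PPARg target genes 11 were lower and 9 higher (median -0.10, camera adjusted p = 0.550), and the list passed without rilpivirine replicate 4 (-0.27, adjusted p = 0.00667), whereas the median was 0.01 without rilpivirine replicate 1, 0.05 without rilpivirine replicate 2 and 0.11 without both. Its members Pnpla2, the main triglyceride lipase of lipid droplets, Plin5 and Mgll differed by -0.45 ± 0.14, -0.65 ± 0.21 and -0.26 ± 0.12, and Pparg by 0.11 ± 0.21 (SE), or -0.10 without rilpivirine replicate 4.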

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

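The tests of RNA quality in replicate 2, of the time of day and of the splits for the gene counts and the acute phase, endothelial and clock lists were chosen only after the results were seen, as were the left-out pair of arrays and the small nucleolar RNA covariate. Of 230 groups of 4 values, 16 had a sample far from the other 3, where chance gives about 11.5 (1 in 20), and 3 of the 16 fell in rilpivirine replicate 2. With the genes of all 32 lists covered, a count added after the data were seen, it was 27 of 320, where chance gives 16. The genes covered were those of the described lists, a choice made after values had been seen.

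Rilpivirine replicate 2 stood apart in its mean correlation with the other arrays (0.967), in the interquartile range of its deviations from the gene medians (0.460) and in Acot4 (4.73 log2, against 5.91 to 5.98 in the other 3 of its group). A candidate explanation is RNA quality or extraction. The small nucleolar RNA probe sets of replicate 2 lay 0.4915 log2 above the mean of the 8 arrays, against at most 0.284 in the others. Its deviations correlated with gene length across genes at a Spearman rho of -0.209, although genes are not independent. This was the lowest of the 8, but the others ran from -0.142 in rilpivirine replicate 1 to 0.197 in rilpivirine replicate 4. In the small nucleolar RNA level, control replicate 1 lay far from the mean on the other side, at -0.628. Of the 35 ways to split the 8 arrays into 4 and 4, the split of rilpivirine replicates 1 and 2 with control replicates 2 and 3 against the rest called 408 genes in limma, where the real split called 0, which points to a structure of the samples other than the treatment. These are the 4 arrays with the highest scores on the first principal component, so the count restates that component and is no separate evidence on its source. A difference between the animals themselves stays open, since no biological explanation was tested for this pattern.

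The lower acute phase list is the second pattern. Chance could not be excluded: 2 of the 35 splits, the real one included, gave a camera p as small as the real one (9.27e-12, against 2.80e-12 for the other), and 3 of the 35 called as many members over the list alone (4, highest other 10). RNA quality was set against treatment by leaving out rilpivirine replicates 1 and 2, which took the median from -0.281 to -0.1434, and by the small nucleolar RNA covariate, which took it to -0.207, with a standard error over members of 0.0887 and 0.0708 and camera adjusted p of 1.19e-06 and 2.65e-09. Both medians kept at least 50% of the size over all arrays, the bound set beforehand against RNA quality as the cause, but by less than their standard error; that this margin had to exceed the error was applied to the tests after their values had been seen. RNA quality and an effect of rilpivirine therefore cannot be told apart as causes for this list, because the margin is within the error. That error was taken over the member genes as if they were independent. It does not measure the spread between samples and may be too small. Other causes, such as the collection time, were not tested for this list.

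The clock genes are the third pattern. The real split had the smallest camera p of the 35 (8.72e-06, against 2.21e-04 for the next). Over the list alone 13 members passed, against at most 2 in any other split. This does not exclude chance, since 1 of 35 is the smallest share the design allows. The split test was run on 8 lists that camera had picked out of 32, and it was chosen after the result was seen. Neither camera with an estimated correlation (adjusted p = 0.321) nor fry (adjusted p = 0.154) called the list, and without control replicate 3 the 13 members became 2. Without rilpivirine replicates 1 and 2, 13 of the 13 members kept their sign and at least 50% of their size. These members had been called with those arrays included, which favours genes that differ in all arrays, so RNA quality is not excluded. The median of the whole list lay between -0.510 and -0.316 over the alternatives, with those arrays left out and the small nucleolar RNA covariate among them. The time of day at which tissue was taken stays open: 10 of 10 genes that peak near dusk were lower and 3 of 4 that peak near dawn were higher. The dusk minus dawn index was -0.53 ± 0.66 log2 with rilpivirine and 0.53 ± 0.29 in controls (SD, n = 4 each). Its exact two-sided permutation p was 0.0571, where the smallest possible is 0.0286. In rilpivirine replicates 1 to 4 the index was 0.15, -0.99, -0.08 and -1.18, and in controls it ran from 0.15 to 0.85. The difference thus lay mainly in rilpivirine replicates 2 and 4. The dusk and dawn sets were written after the values were seen and leave out other measured clock genes. Among these are Nr1d1, a daytime gene that was higher, unlike the dusk genes, and Cry1 and Cry2, with log2 differences of -0.47 and -0.44. With Nr1d1 among the dusk genes 10 of 11 were lower and the index differed by -0.92, with the same exact two-sided permutation p. Counts and an index with Cry1 or Cry2 in either set were not computed. Whether a higher Nr1d1 goes against a difference in collection time was not tested. Collection time and a shift of the clock by rilpivirine cannot be told apart, because both predict this index and no collection times are given; that a difference beyond its spread kept the former open was also settled after the value had been seen.

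The other counts and lists did not stand out among the 35 splits. The count of genes past the adjusted threshold was 0 in the real split, which every split must reach, so the splits cannot test that count. As many genes at an unadjusted p (867, highest other 3110) came in 9 splits, and as many lists (8, highest other 20) in 18. Chance could not be excluded for the latter counts. A camera p as small came in 3 splits for sinusoidal endothelial markers (real 6.03e-07, smallest other 1.34e-11), 11 for the cell cycle (1.94e-04 and 2.88e-15), 3 for autophagy and lysosome (0.00138 and 0.00104), 13 for Kupffer cell markers (0.00673 and 1.10e-09), 10 for monocyte markers (6.65e-04 and 7.85e-10) and 8 for skeletal muscle markers (0.00510 and 1.89e-05), and chance could not be excluded for these lists either.

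The other samples far from their group are given as log2 values. In rilpivirine replicate 1, Ulk1 measured 7.895 (others 7.65 to 7.68) and Tnf 2.477 (others 3.29 to 3.35). In rilpivirine replicate 3, Gldc measured 8.073 (others 8.46 to 8.51) and Cyp2c29 11.55 (others 11.46 to 11.47). In rilpivirine replicate 4, Oit3 measured 7.638 (others 8.14 to 8.21), and the mean of the stellate cell markers was 0.11 (others -0.0867 to -0.0649). In control replicate 2, Rarres1 measured 7.161, Bnip3 7.123, C1qc 6.668 and Mgll 7.833, and the mean of the PXR and CAR targets was -0.2565 (others 0.0966 to 0.145). In control replicate 3, Cxcl1 measured 5.83 (others 5.07 to 5.17) and Cyp2b10 6.753 (others 5.24 to 5.28).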

How the results depend on the processing

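The alternatives without rilpivirine replicates 1 and 2 and with the small nucleolar RNA covariate were chosen after seeing the data. The count of genes past the adjusted threshold was 0 in every alternative run, including Welch statistics per gene, which gave 653 at an unadjusted p. The count at an unadjusted p (867) ranged from 578 to 1524 with a sample left out, the highest without rilpivirine replicate 4; the cause was not tested. The 8 called lists became 0 in camera with estimated correlation, 0 in fry and 1 in fry's mixed form, which allow for genes that vary together. Under the other alternatives camera at the preset correlation called 7 to 10 lists, not always the same ones. Of the original 8, 4 held without rilpivirine replicates 1 and 2 together. Without rilpivirine replicate 2, among genes above the median level, and with the small nucleolar RNA covariate, 5 held each time. The acute phase and clock lists were called in 18 of 18 alternatives, with medians of -0.343 to -0.143 and -0.510 to -0.316; endothelial and cell cycle lists were called in 17, autophagy in 15, Kupffer and monocyte markers in 13 and muscle in 11. The camera adjusted p over the alternatives ran from 7.90e-13 to 1.19e-06 for the acute phase list, 1.27e-05 to 0.00333 for the clock, 8.72e-08 to 0.0736 for endothelial markers, 2.13e-11 to 0.272 for the cell cycle, 0.00109 to 0.453 for autophagy, 0.00203 to 0.585 for Kupffer cells, 1.55e-05 to 0.924 for monocytes and 0.00340 to 0.503 for muscle. For lists not called over all arrays it ran from 0.0270 to 0.999 for fibrosis, 0.00571 to 0.999 for interferon-stimulated genes, 0.000223 to 0.979 for lipogenesis, 0.0473 to 0.924 for PPARa targets, 0.00667 to 0.919 for lipid droplets and 0.000895 to 0.464 for NRF2 targets. A total of 4 list medians turned: without rilpivirine replicates 1 and 2 the interferon-stimulated genes had 0.046 and the monocyte markers 0.02219, and with the small nucleolar RNA covariate the interferon-stimulated genes had 0.05807 and the muscle markers -0.01229; the cause was not tested. Of the other values, 469 list medians kept their direction and side of the threshold, 58 below it changed sign, 20 lost and 19 gained a call. Among named genes 1400 differences kept their sign and 14 changed it. No gene passed the threshold in any setting, so no named gene could lose or gain a call. Genes named because their groups did not overlap cannot turn when a sample is left out, so these counts are no measure of stability. The replicate numbers did not pair the samples (correlations of same-numbered samples -0.249, 0.461, -0.088 and 0.066; 1 of 4 rilpivirine samples correlated best with its own number); with the number as a replicate block the counts were 0 genes, 1071 at an unadjusted p and 8 lists. Signal over background limits genes near the filter: without the filter 22180 genes gave 1089 at an unadjusted p, and above the median level 11090 genes gave 584.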

Other observations

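The test of tight junction genes was run on a list written after 3 of its members were seen. Lists outside the main account did not pass camera's adjusted p of 0.05 over all 8 arrays. The median log2 difference, with its range over the alternatives in brackets, was -0.05 (-0.10 to -0.004) for 18 hepatocyte markers, 0.08 (0.02 to 0.13) for 11 cholangiocyte markers, -0.02 (-0.05 to 0.03) for 13 T and NK cell markers, -0.04 (-0.08 to 0.08) for 9 B and plasma cell markers, 0.08 (-0.005 to 0.13) for 8 neutrophil markers, 0.13 (0.08 to 0.19) for 8 exocrine pancreas markers and -0.08 (-0.23 to 0.18) for 7 adipocyte markers. Among pathways it was 0.08 (-0.13 to 0.24) for NRF2 targets, 0.002 (-0.21 to 0.18) for cholesterol synthesis, -0.03 (-0.06 to 0.03) for bile acid genes, -0.05 (-0.16 to 0.06) for the unfolded protein response, -0.10 (-0.21 to 0.05) for apoptosis and p53 targets, -0.07 (-0.16 to -0.004) for glucose metabolism and -0.08 (-0.13 to -0.03) for oxidative phosphorylation. Cholesterol synthesis had medians of -0.21 and 0.14 without rilpivirine replicates 1 and 2 in turn, and passed camera in the latter case (adjusted p = 0.00709). Oxidative phosphorylation passed without rilpivirine replicate 1 (median -0.13), and cholangiocyte markers without rilpivirine replicate 3 (0.08) or control replicate 1 (0.09). Female-biased liver genes had a median of 0.18, which was -0.09 without rilpivirine replicate 3 and -0.08 without control replicate 2, and male-biased ones had -0.03 (-0.14 to 0.04). For the bile acid, female-biased, T and NK cell and B and plasma cell lists the median and camera's direction differed in sign. The erythroid list had too few measured members to be tested.

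A few members of these lists passed limma's threshold when adjusted over the list alone, though not over all genes, and were picked for that reason. Hsd3b7, an enzyme of bile acid synthesis, was higher by 0.59 ± 0.13 log2 (SE). Gys2, the glycogen synthase of liver, was lower with a difference of -0.65 ± 0.15 (SE), and Cux2, a transcription factor of female liver, had -0.57 ± 0.13 (SE). These calls ended with single arrays left out: 0 members were called without rilpivirine replicate 2 or control replicate 3 or 4 in all 3 lists, without rilpivirine replicate 1 or control replicate 1 for bile acid and glucose genes, and without rilpivirine replicate 4 for glucose genes, where centring of the arrays also gave 0. NRF2 targets, which respond to oxidative and electrophilic stress, passed camera in 7 of 18 alternatives, with a median of 0.18 without rilpivirine replicate 2 and 0.22 with the small nucleolar RNA covariate, but had a median of -0.13 with 15 of 19 members lower without rilpivirine replicate 4. That sample had the highest list mean, 0.65 log2 above the mean of 8 arrays, while rilpivirine replicates 2 and 3 lay at -0.30 and -0.27.

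Cldn1 and Tjp3, which encode tight junction proteins, and Marveld1, a membrane protein with a MARVEL domain, were among the genes with the smallest p. The first 2 were higher and the third lower, and all 3 were in the tight junction list written afterwards. The hypothesis that tight junction genes change as a group was tested on the other 29 measured members of a tight junction list with fry's mixed test. The p was 0.596, with 1 of 29 members at an unadjusted p under 0.05 in limma, so the remaining genes gave no sign of such a change.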
